A study of Mus musculus with 18 samples.

How the data were processed

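Gene expression was measured by bulk RNA sequencing in 18 libraries of mouse bone marrow-derived basophils, 3 in each of 6 groups: WT and libraries labelled TTP-KO, each after control OVA for 2 h and TNP-OVA for 2 h or 4 h. The deposited table holds estimated counts per gene (expected counts of the kind RSEM gives), with no normalization: values have 2 decimals and library sums differ. The submitters' processing notes name cutadapt 3.5, STAR 2.7.10a, RSEM 1.3.1, R 4.4.1 and R 4.4.0 and the genome build GRCm39, without saying what each was used for, and the annotation release and strand setting are not given there. The control columns of the table are named as unstimulated and were matched to the control OVA libraries. No 2 libraries of a group were copies of each other (18 pairs compared within groups, chi-square per degree of freedom from 2.96 to 6.77). The most abundant gene, a ribosomal RNA gene, took from 7.78% to 11.0% of a library's counts.

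Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups (14076 of 56413, 23836 having no count in any library), scaled by the trimmed mean of M values (TMM), and fitted with edgeR's robust quasi-likelihood model with a mean for each group, which leaves 12 residual degrees of freedom. The biological coefficient of variation was 0.0905. Of the 12 contrasts, 3 compared genotypes within a condition, 6 compared conditions within a genotype and 3 were interactions. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and standard errors are the log2 fold change divided by the square root of the F statistic. A comparison of 3 libraries with 3 by exact permutation cannot give a p below 0.1, so tests rest on the model fitted across genes.

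The design, the rule for naming genes, the gene lists and the alternatives were chosen before the data were examined. For each genotype comparison within a condition and each WT stimulation comparison, the rule took the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 2 and all 3 libraries of one group above all 3 of the other. For each interaction it took the 6 smallest p in each direction, and for each list up to 4 members past the threshold with the largest change, or the 2 smallest p where none passed. Genes known only by an identifier or a clone name were counted but not named. Genes followed from one comparison into another, and those said to be chosen after their values were seen, fall outside the rule. Near-identical copies share reads, so values of H2 genes, Hba-a1 and Hba-a2, Akr1c12 and Akr1c13, Lilrb4a, Ear genes, Bcl2a1 genes and immunoglobulin segments are uncertain.

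The 29 lists comprised 18 of functions (reported TTP target mRNAs, cytokines and growth factors, chemokines, immediate early genes, NF-kB targets and feedback, calcium and NFAT pathway, FceRI signalling components, mRNA decay and RNA-binding regulators, lipid mediators and histamine, granule proteins and exocytosis, apoptosis regulators, surface and costimulatory receptors, interferon response, cytokine signalling feedback, glycolysis and hypoxia response, cholesterol synthesis, unfolded protein and heat shock response, and cell cycle) and 11 of markers (basophil, mast cell, neutrophil and granulocyte precursor, monocyte and macrophage, dendritic cell, NK cell and innate lymphoid cell, T cell and B cell, eosinophil, erythroid, megakaryocyte and platelet, and haematopoietic progenitor). They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 87 tests for the genotype comparisons and 58 for WT stimulation. Camera with an estimated correlation and fry were run beside it. Estimated correlations of some lists lay above the preset value, such as 0.132 for dendritic cell markers between genotypes in control. For such lists the p at the preset correlation can be too small. Hdc, Ccr2 and other genes belong to more than 1 list. Many reported TTP targets are also in the lists of cytokines, chemokines, immediate early genes or NF-kB targets. Results of these lists are therefore not independent of each other.

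The model was tested on simulated counts for all 18 libraries, drawn from negative binomial distributions with the measured group means and fitted dispersions. The control groups shared their means except for genes changed on purpose, which were drawn from those with a mean log2 CPM of at least 2. Of 100 genes changed 1.5-fold edgeR recovered 65, and of 100 changed 2-fold it recovered 92, with 12 other genes called. DESeq2 1.42.0 recovered 59 and 91, also with 12 others. Of 50 random lists, camera gave none and fry 5 a p under 0.05. Simulated genes were drawn independently, so this does not measure false calls for lists whose members vary together. The alternatives were relative log expression (RLE) scaling, no filter, DESeq2, only the libraries of the groups compared, a replicate block, and leaving out each library. The 3' UTR motif and gene neighbours were read from a GRCm38 annotation (GENCODE M21), joined by gene identifier, since that build differs from the authors' GRCm39. Of the genes tested, 82.4% had an annotated 3' UTR. Motif and neighbour tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Raw reads were not used here. Some results that the naming rule took are not reported here.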

Results

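Basophils are rare granulocytes that carry the high-affinity receptor for IgE and release histamine, lipid mediators and cytokines when antigen links their bound IgE. The cells studied here were grown from mouse bone marrow for 7 days with interleukin-3 at 0.3 ng/mL. They were coated on day 6 with IgE against the hapten TNP (1 µg/mL), and enriched on magnetic beads through the surface protein CD49b. They came from wild-type (WT) mice or were labelled TTP-KO, for tristetraprolin, the RNA-binding protein encoded by Zfp36, which binds AU-rich elements in messenger RNA and promotes its decay. Each genotype received plain ovalbumin (OVA) for 2 h as control, or TNP-coupled OVA (TNP-OVA) for 2 h or 4 h, both at 10 ng/mL. Bulk RNA was sequenced from 3 libraries in each of the 6 groups, 18 libraries in all, to ask how the loss of tristetraprolin alters gene expression after antigen stimulation.

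Library totals ran from 5516600 to 12733000 estimated counts. The group means were 7586600 ± 1973200 counts (SD, n = 3) for WT control and 7655300 ± 1468900 for TTP-KO control. At 2 h they were 7885100 ± 908950 for WT and 7804000 ± 579030 for TTP-KO, and at 4 h 11256000 ± 1415400 and 9467900 ± 1919800. Mitochondrially encoded genes took between 1.78% and 2.09% of counts in the group means, and ribosomal protein genes between 2.20% and 2.94%. Of 56413 genes in the table, 14076 were abundant enough to test, and these held 99.8% of the counts. The first principal component carried 38.6% of the variance and separated the stimulated libraries from the controls, and the second carried 20.4% and separated 2 h from 4 h. Errors beside log2 fold changes are standard errors and those beside counts per 1e6 (CPM) are SDs, with 3 libraries in each group throughout. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical.

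**Figure D1:**
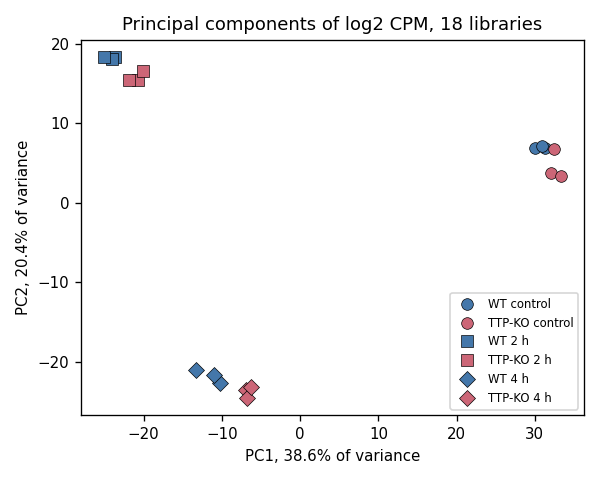
Principal components of log2 CPM for the 18 libraries, with PC1 (38.6% of the variance) on the horizontal axis and PC2 (20.4%) on the vertical axis. Circles are control libraries, squares 2 h and diamonds 4 h of TNP-OVA, in blue for WT and red for libraries labelled TTP-KO, and the 3 conditions lie apart.

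Zfp36 itself was transcribed in every library. In control cells it stood at 237 ± 11.4 CPM in WT and 224 ± 4.46 CPM in libraries labelled TTP-KO. With TNP-OVA it stood at 2 h at 448 ± 10.6 and 564 ± 9.92 CPM, and at 4 h at 295 ± 22.7 and 324 ± 23.9 CPM. Antigen raised it in both genotypes at 2 h, by a log2 fold change of 0.92 ± 0.05 in WT (edgeR adjusted p = 2.32e-14) and 1.33 ± 0.05 in libraries labelled TTP-KO (adjusted p = 5.13e-18). Between genotypes the log2 difference, TTP-KO over WT, was -0.08 ± 0.05 in control cells (edgeR adjusted p = 0.601), 0.33 ± 0.05 at 2 h (adjusted p = 3.16e-04) and 0.14 ± 0.05 at 4 h (adjusted p = 0.151). The RNA was therefore not lower in the libraries labelled TTP-KO. The labels do not say which part of the gene was altered, so its RNA level does not check the genotype labels, and every direction below rests on those labels. Gm44710, the tested gene next to Zfp36 on the opposite strand, had estimated counts between 2.58 and 17.6 per library. The strand setting of the counting is not given in the sources used here. Whether antisense reads entered the Zfp36 counts therefore cannot be told from these values.

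**Figure D2:**
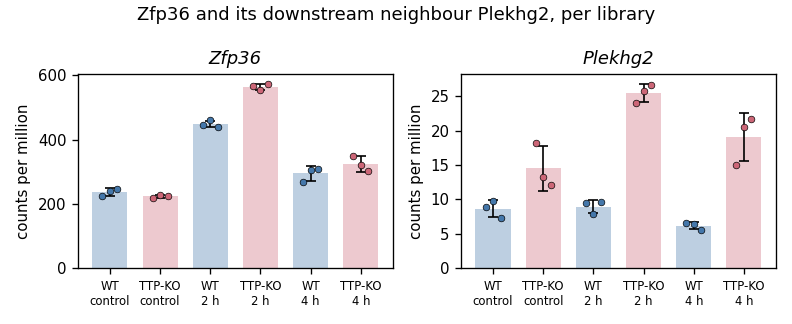
CPM of Zfp36 and of Plekhg2, the next gene downstream on the same strand, in each library (points), with group means (bars) and SDs (error bars, n = 3). Zfp36 is present at all conditions in both genotypes, while Plekhg2 is higher in the libraries labelled TTP-KO, with means of 14.5, 25.4 and 19.1 CPM against 8.66, 8.95 and 6.17 CPM in WT.

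Cytokine and transcription factor genes were among the largest increases after 2 h of antigen stimulation in WT basophils. Il4, the type 2 cytokine basophils are best known for, climbed from 265 ± 9.39 to 2531 ± 279.7 CPM. Il13 went from 96.8 ± 6.06 to 825 ± 35.2 CPM, and the chemokine gene Ccl3 from 2212 ± 75.5 to 18400 ± 245 CPM. The genes with the largest increases were Csf2, encoding GM-CSF (log2 fold change 3.86 ± 0.29), the nuclear receptor Nr4a3 (3.81 ± 0.06), the transcription factor Egr3 (3.45 ± 0.08) and Il3 (3.43 ± 0.34). They were followed by the receptor tyrosine kinase Mst1r (3.38 ± 0.23), the transcription factor Fosl1 (9.88-fold), Il4 (3.26 ± 0.08), Cryba4 (3.17 ± 0.35) and Tgm1 (3.15 ± 0.13). The largest decreases were in Nxpe4 (-2.56 ± 0.16), Pik3ip1, an inhibitor of PI3-kinase (-2.29 ± 0.21), St6galnac5 (-1.98 ± 0.26) and the prostaglandin receptor Ptgfr (-1.97 ± 0.30). Next came Zfp831 (-1.95 ± 0.20), Tbc1d4 (-1.94 ± 0.10), Ssh2 (-1.90 ± 0.06) and the ubiquitin ligase Rnf125 (-1.83 ± 0.11). In total 4944 genes differed from control (2512 higher and 2432 lower, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1051 of them at least 2-fold. The genes taken by size of change had all 3 stimulated libraries on the same side of all 3 controls, as did 43.4% of genes tested, where chance gives 10%. The rule for naming took 3 more genes, left out here because leaving out single libraries ended their calls.

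Most of the stimulus-response lists fixed beforehand, which share genes, rose together at 2 h. Of 33 measured messenger RNAs reported as tristetraprolin targets, 26 rose and 2 fell (28 and 2 adjusted over the list alone, camera adjusted p = 5.72e-77). Csf2, Il3, Il4 and Ptgs2, the inducible cyclooxygenase (3.12 ± 0.09), stood at the top. Of 26 cytokines and growth factors, 19 rose and 2 fell (20 and 2 adjusted over the list alone), including Il13 (3.09 ± 0.06), with camera adjusted p = 5.48e-57. Among 33 immediate early genes 28 rose and 3 fell (28 and 4 adjusted over the list alone), Nr4a2 by 3.05 ± 0.16. Among 21 chemokines 11 rose and 4 fell (11 and 4 adjusted over the list alone), Ccl4 by 3.11 ± 0.04, Xcl1 by 2.80 ± 0.33 and Ccl7 by 2.37 ± 0.14. Among 20 genes of cytokine signalling feedback 16 rose and none fell (17 adjusted over the list alone), with Osm at 2.37 ± 0.12, Spry2 at 2.35 ± 0.09 and Socs1 at 2.20 ± 0.06. Of 35 surface and costimulatory receptors 20 rose and 4 fell (20 and 6 adjusted over the list alone), including Pdcd1lg2 (1.67 ± 0.06) and the activation marker Cd69 (1.57 ± 0.08). NF-kB targets split 14 higher and 5 lower of 30 (15 and 8 adjusted over the list alone), led by Pim3 (2.22 ± 0.07) and Nfkbid (1.75 ± 0.07), with camera adjusted p = 0.00252.

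Lists of mediator synthesis, signalling and housekeeping pathways moved in different directions, or not as a list, at 2 h in WT. Hdc, the histamine-forming enzyme, rose by 1.72 ± 0.04 to 6709 ± 141 CPM. Of this list, 7 of 22 genes for lipid mediators and histamine rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.017, and 0.0586 with no expression filter). Of 23 granule and exocytosis genes 11 rose and 3 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.145 with an estimated correlation). Gzmb stood at 1.98 ± 0.09 and Serpinb1a at 1.28 ± 0.04, against Rab27a at -1.18 ± 0.08. Of 21 cholesterol synthesis genes 13 rose and 2 fell (14 and 3 adjusted over the list alone), Hsd17b7 by 1.41 ± 0.15 (camera adjusted p = 0.00334, adjusted p = 0.0594 with an estimated correlation). Of 35 cell cycle genes 1 rose and 14 fell (1 and 16 adjusted over the list alone), Kif2c by -1.04 ± 0.21 (camera adjusted p = 0.0296, adjusted p = 0.147 with an estimated correlation). Components of IgE receptor signalling went both ways, 12 up and 12 down of 38 (14 and 12 adjusted over the list alone, camera adjusted p = 0.797). The adaptor Lcp2 was at 1.29 ± 0.05 and the phosphoinositide kinase Pik3cd at -1.08 ± 0.09. The calcium and NFAT pathway (4 up, 8 down of 25, camera adjusted p = 0.797, Orai1 1.43 ± 0.05 and Nfatc1 1.07 ± 0.06) did not stand apart as a list. Nor did messenger RNA decay regulators (16 up, 6 down of 44, adjusted p = 0.206), where the Zfp36 relative Zfp36l1 rose by 1.32 ± 0.05. Apoptosis regulators did not either (7 up, 9 down of 30, adjusted p = 0.325), though Pmaip1 rose by 1.85 ± 0.07 and Bmf changed by -1.48 ± 0.15. None of the 11 lists of cell type markers passed the camera test at 2 h in WT, though mast cell markers did with no expression filter. By fry 21 of the 29 lists passed in this comparison, more than the 18 lists of functions, so some marker lists passed that test.

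After 4 h in WT the largest increases were in chemokine, cytokine and other genes. Ccl24, an eosinophil attractant, went from 3.71 ± 0.90 to 48.3 ± 2.89 CPM (log2 fold change 3.74 ± 0.19). Other large increases were in Il3 (3.83 ± 0.33), the serine protease gene Prss37 (3.49 ± 0.13), the costimulatory receptor Tnfrsf9 (3.40 ± 0.24) and Csf2 (3.39 ± 0.29). After these came the retinal dehydrogenase Aldh1a3 (3.06 ± 0.22), Ccl1 (3.01 ± 0.21), Ptprf (2.97 ± 0.22) and Scimp (2.97 ± 0.18). Decreases were led by Nxpe4 (-2.86 ± 0.16), Pik3ip1 (-2.20 ± 0.20), the fractalkine receptor Cx3cr1 (-2.15 ± 0.24) and Tmem71 (-2.02 ± 0.10). Further decreases were in St6galnac5 (-1.98 ± 0.25), Rassf3 (-1.92 ± 0.06), Rnd1 (-1.89 ± 0.22), Id3 (-1.86 ± 0.12), Tbc1d4 (-1.86 ± 0.09) and Alox12e (-1.84 ± 0.14). Fcer1a, the IgE-binding chain of the receptor, fell from 887 ± 53.0 to 465 ± 16.0 CPM (-0.93 ± 0.04, edgeR adjusted p = 2.18e-16). Altogether 5350 genes differed from the 2 h control (2758 higher, 2592 lower, 903 at least 2-fold), and all 3 libraries of the 2 groups lay apart for 49.1% of genes, where chance gives 10%. Stimulation time and the length of culture after OVA are not separated here, since the control was taken at 2 h alone, and 1 more gene the rule took lost its call without single libraries.

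At 4 h 5 of the lists still rose, with camera adjusted p between 4.09e-35 and 3.75e-14. They were the tristetraprolin targets (26 up, 3 down of 33, 27 and 3 adjusted over the list alone) and cytokines (19 up, 2 down of 26, the same adjusted over the list alone). Chemokines followed (12 up, 4 down of 21, the same adjusted over the list alone), then immediate early genes (24 up, 6 down of 33, 26 and 6 adjusted over the list alone) and cytokine signalling feedback (16 up, 1 down of 20, 16 and 3 adjusted over the list alone). Examples were Hbegf (2.38 ± 0.12), Inhba (2.15 ± 0.08), Lif (2.00 ± 0.12), Socs1 (2.27 ± 0.06) and Cish (1.79 ± 0.07). Glycolysis and hypoxia genes, 15 of 26 up and 4 down, included the lactate transporter Slc16a3 (1.09 ± 0.05) and the glucose transporter Slc2a1 (0.99 ± 0.06). The list had camera adjusted p = 0.017 and adjusted p = 0.331 with an estimated correlation. Of 27 unfolded protein and heat shock genes 15 rose and 5 fell, with Hsph1 at 0.96 ± 0.10 and Ddit3 at -0.79 ± 0.08 (camera adjusted p = 0.0242, adjusted p = 0.0913 with an estimated correlation). Surface receptors had 17 up and 9 down of 35 (18 and 9 adjusted over the list alone, camera adjusted p = 0.0242, adjusted p = 0.302 with an estimated correlation). Cell cycle genes had 1 up and 14 down of 35 (the same adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.16 with an estimated correlation). This call ended without replicate 1 of WT control or replicate 3 of WT at 4 h (0.0584 and 0.0511). Interferon response genes went 11 up and 5 down of 34 (camera adjusted p = 0.153), with Usp18 at 1.42 ± 0.17 and Cxcl10 at -1.35 ± 0.12. Markers of neutrophils and their precursors were lower in these WT libraries at 4 h, 10 of 17 down and 1 up (camera adjusted p = 0.0237, adjusted p = 0.291 with an estimated correlation). Retnlg was at -0.90 ± 0.08 and Ngp at -0.58 ± 0.11, but Chil3 at 1.24 ± 0.08.

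The libraries labelled TTP-KO responded to antigen with a similar number of genes, 4852 at 2 h (2510 higher, 2342 lower) and 4932 at 4 h (2577 higher, 2355 lower). Genes named above were followed in them. At 2 h Il4 rose by 3.27 ± 0.08, Il13 by 3.68 ± 0.06, Ccl3 by 3.61 ± 0.05, Nr4a3 by 3.25 ± 0.06, Csf2 by 2.82 ± 0.25 and Il3 by 1.46 ± 0.37 on the log2 scale. At 4 h Il4 was still up by 2.21 ± 0.08, against 1.57 ± 0.08 in WT. From 2 h to 4 h, 4382 genes changed in WT (2140 higher, 2242 lower) and 4334 in libraries labelled TTP-KO (2050 higher, 2284 lower). Over that interval Il13 fell by 2.46 in WT and by 3.11 in libraries labelled TTP-KO, Nr4a3 fell by 2.18 and 2.08, and Il4 fell by 1.69 and 1.06 on the log2 scale. The mannose receptor gene Mrc1 rose by 0.29 ± 0.07 and 1.11 ± 0.07.

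**Figure D3:**
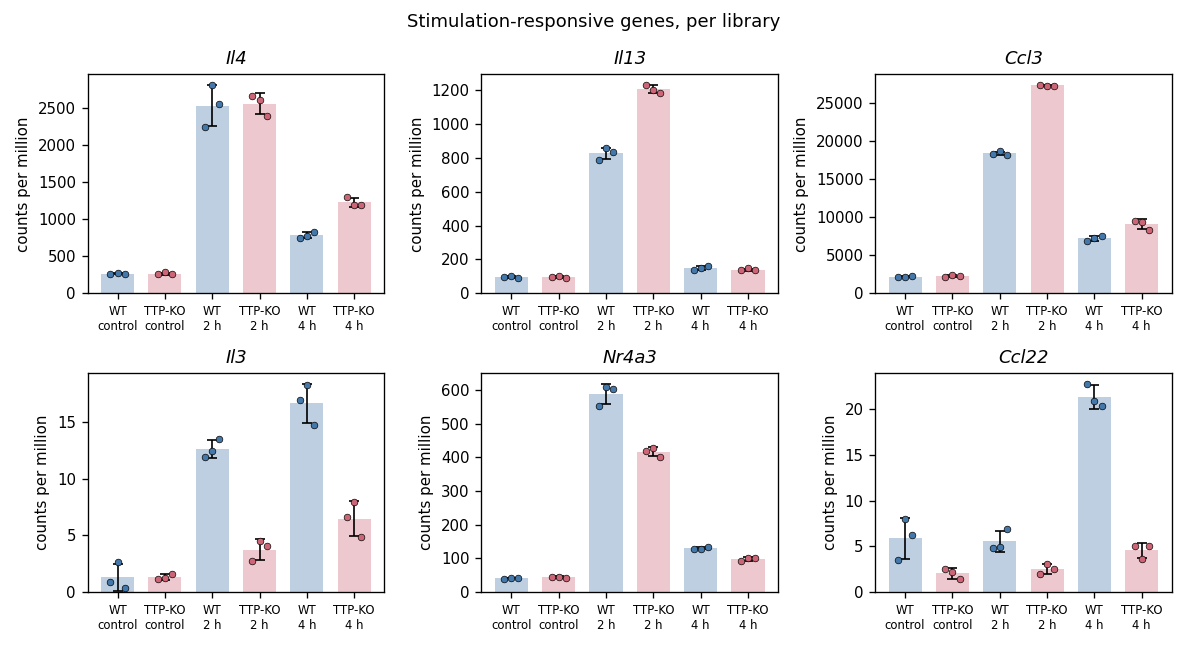
CPM of Il4, Il13, Ccl3, Il3, Nr4a3 and Ccl22 in each library (points), with group means (bars) and SDs (error bars, n = 3), for control, 2 h and 4 h of TNP-OVA in WT (blue) and in libraries labelled TTP-KO (red). At 2 h Il13 stands at 825 and 1205 CPM in the 2 genotypes and Il3 at 12.6 and 3.74 CPM, and at 4 h Il4 stands at 785 and 1225 CPM.

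In unstimulated basophils the differences between genotypes included neutrophil granule genes and B cell genes. Neutrophil granule genes were higher, with Camp, the cathelicidin, at 34.0 ± 4.33 against 17.4 ± 2.64 CPM (log2 fold change 0.99 ± 0.13, edgeR adjusted p = 2.48e-05). Ltf, lactoferrin, was at 0.86 ± 0.08 and Ngp at 0.80 ± 0.11. B cell genes were lower, including Fcmr, the IgM Fc receptor (-1.52 ± 0.28), Ms4a1, which encodes CD20 (-1.13 ± 0.22), and Cd79b (-1.13 ± 0.17). Also lower were the chemokine Ccl22 (-1.52 ± 0.28), the protease Adam19 (-1.41 ± 0.24), Dcstamp (-1.28 ± 0.24) and Npy (-1.28 ± 0.21). The cytokine Il1a was higher, by 0.68 ± 0.08 (edgeR adjusted p = 3.05e-06), and so was the transcription factor Maff (0.52 ± 0.09). Il13 stood at -0.04 ± 0.06 (adjusted p = 0.874) and Ccl3 at 0.02 ± 0.05 (adjusted p = 0.912), and Il4 at 264 ± 15.5 against 265 ± 9.39 CPM. In all, 232 genes differed (58 higher and 174 lower, edgeR, adjusted p under 0.05), 26 of them at least 2-fold. The count was 145 without replicate 3 of the TTP-KO control group and 149 when the spread was estimated from these 6 libraries alone. A further 7 genes taken by the naming rule, Plekhg2 among them, lost their calls when single libraries were left out.

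By list, in control cells, 7 of 17 neutrophil and granulocyte precursor markers were higher and none lower (10 higher adjusted over the list alone, median 0.49, camera adjusted p = 2.67e-21). Of 9 T and B cell markers 5 were lower (8 adjusted over the list alone, median -1.04, adjusted p = 1.34e-16), among them Ms4a1, Cd79b and Cd79a at -1.04 ± 0.16. Of 8 dendritic cell markers 4 were lower (the same adjusted over the list alone, 1 higher, camera adjusted p = 9.73e-34). All 4 serve class II antigen presentation. They were H2-Eb1 (-0.87 ± 0.05, 197 ± 6.11 against 360.3 ± 7.24 CPM), H2-Ab1 (-0.75 ± 0.04), H2-Aa (-0.71 ± 0.04) and Cd74 (-0.59 ± 0.04). Of 8 mast cell markers 2 were lower (5 adjusted over the list alone), the tryptase Tpsb2 (-0.86 ± 0.06) and the chymase Cma1 (-0.62 ± 0.12), with camera adjusted p = 2.04e-10. The 12 basophil markers gave 1 higher, Prss34 at 0.17 ± 0.03, and 3 lower, including Cyp11a1 at -0.22 ± 0.04 (1 and 3 adjusted over the list alone, camera adjusted p = 0.157, and 0.0245 without replicate 1 of WT control). NF-kB targets were lower as a list, 3 of 30 with none higher (8 adjusted over the list alone, camera adjusted p = 3.20e-09), led by Cd83 (-0.65 ± 0.08). No single one of 35 cell cycle genes passed over all genes, but 8 were higher and 1 lower adjusted over the list alone, and the list was higher (median 0.15, camera adjusted p = 6.58e-07). The reported tristetraprolin targets did not move as a list, with 2 higher and 3 lower of 33 (6 and 3 adjusted over the list alone, camera adjusted p = 0.577). With an estimated correlation, camera adjusted p was 5.31e-04 for neutrophil, 1.67e-04 for T and B cell, 6.61e-05 for dendritic cell and 2.80e-04 for mast cell markers. In the same test it was 7.40e-04 for NF-kB targets and 0.00471 for cell cycle genes.

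In the same control comparison 6 further lists passed camera with the preset correlation only. Surface receptors had 5 lower of 35, such as Ccr2 (-0.45 ± 0.07) and Il7r (-0.31 ± 0.05), with adjusted p = 0.0844 with an estimated correlation. The interferon response (median -0.19) had adjusted p = 0.146 with an estimated correlation, and cholesterol synthesis (median -0.12) 0.0707. In the same test monocyte and macrophage markers (5 higher and 2 lower of 16, Apoe 0.39 ± 0.04) had 0.0842, erythroid markers (median -0.59) 0.0686 and megakaryocyte and platelet markers (median -0.23) 0.199. The last 2 also missed the threshold without replicate 3 of the TTP-KO control group, at camera adjusted p = 0.0701 and 0.125.

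At 2 h of TNP-OVA, the genotypes parted in several cytokine and early response genes. Ccl3 reached 27350 ± 72.2 CPM in libraries labelled TTP-KO against 18400 ± 245 CPM in WT (log2 fold change 0.57 ± 0.05, edgeR adjusted p = 1.37e-06). Il13 reached 1205 ± 23.1 against 825 ± 35.2 CPM (0.55 ± 0.05, adjusted p = 8.58e-08). The growth factor Hbegf (0.60 ± 0.10), Il1a (0.43 ± 0.07) and Ptgs2 (0.45 ± 0.08) were higher too, as was Il6 (0.41 ± 0.06), chosen after its values were seen. Il3 went the other way, at 3.74 ± 0.92 against 12.6 ± 0.81 CPM (-1.75 ± 0.29, adjusted p = 7.27e-04). The nuclear receptors Nr4a2 (-0.75 ± 0.14), Nr4a3 (-0.50 ± 0.05) and Nr4a1 (-0.33 ± 0.06) were lower. Il4 did not differ beyond the spread (0.01 ± 0.07, adjusted p = 0.958). The largest increases that kept their calls without any single library were Plekhg2, a guanine nucleotide exchange factor (1.51 ± 0.17), Olfml3 (1.41 ± 0.29), Ndufb4 (1.34 ± 0.26), Camp (1.03 ± 0.13) and Ngp (0.97 ± 0.11). The largest decreases that likewise kept their calls were in Il3, the B cell transcription factor Spib (-1.68 ± 0.23), Ms4a1 (-1.40 ± 0.23) and Hba-a2 (-1.11 ± 0.20). The comparison called 393 genes (128 higher, 265 lower, 28 at least 2-fold), 228 without replicate 3 of WT at 2 h and 259 without replicate 1 of TTP-KO at 2 h. The calls of 11 other genes the rule took ended when single libraries were left out.

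Among genes called at 2 h, more tristetraprolin targets and cytokines were higher than lower, and the immediate early genes were all lower. Of the 33 reported targets 6 were higher and 2 lower (11 and 2 adjusted over the list alone, median 0.14, camera adjusted p = 1.96e-06, adjusted p = 0.084 with an estimated correlation). Of 26 cytokines 5 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 8.11e-04, adjusted p = 0.175 with an estimated correlation). Immediate early genes had 9 lower of 33 and none higher (11 adjusted over the list alone, camera adjusted p = 1.67e-06), with Ier5 at -0.27 ± 0.05 beside the Nr4a genes. NF-kB targets had 7 lower of 30 and none higher (14 and 1 adjusted over the list alone, adjusted p = 2.59e-07), such as Cd83 (-0.61 ± 0.08) and Cd40 (-0.45 ± 0.09). Surface receptors had 9 lower and 1 higher of 35 (13 and 2 adjusted over the list alone), with adjusted p = 0.0695 with an estimated correlation. Cholesterol synthesis had 2 lower of 21 (4 adjusted over the list alone), with the master regulator Srebf2 at -0.33 ± 0.07 (camera adjusted p = 8.99e-05). Among granule genes Gzmb was lower (-0.59 ± 0.09) and Prss34 higher (0.20 ± 0.03), with no shift of the list (camera adjusted p = 0.351). Markers of other cell types moved beside them. Neutrophil genes had 8 of 17 higher (13 and 1 lower adjusted over the list alone, median 0.38, camera adjusted p = 1.12e-21), and monocyte and macrophage genes 7 higher and 1 lower of 16 (9 and 1 adjusted over the list alone, adjusted p = 1.76e-11). T and B cell genes had 5 of 9 lower (6 adjusted over the list alone, median -0.96, adjusted p = 3.76e-10) and class II genes 4 lower of the 8 dendritic cell markers (5 adjusted over the list alone, H2-Eb1 -0.60 ± 0.05, adjusted p = 4.23e-21). With an estimated correlation, camera adjusted p was 0.0211 for immediate early genes, 0.00152 for NF-kB targets and 0.0123 for cholesterol synthesis. In the same test it was 4.02e-04 for neutrophil, 0.00369 for monocyte and macrophage, and 1.67e-04 for dendritic cell markers.

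Also at 2 h, 5 more lists passed camera with the preset correlation only. They were the interferon response (median -0.12, adjusted p = 0.217 with an estimated correlation) and cell cycle genes (median 0.06, adjusted p = 0.095 with an estimated correlation, and camera adjusted p = 0.0526 and 0.058 without replicate 2 of WT or of TTP-KO at 2 h). The next was mast cell markers (2 lower and 1 higher of 8, Cma1 -0.87 ± 0.13 and Ctsg 0.25 ± 0.04, adjusted p = 0.0614 with an estimated correlation, and 0.0875 with no expression filter). The others were erythroid markers (median -0.33, adjusted p = 0.0842 with an estimated correlation) and platelet markers (median -0.21, adjusted p = 0.223 with an estimated correlation). The erythroid call ended without replicate 3 of WT at 2 h and without replicates 2 or 3 of TTP-KO at 2 h, at camera adjusted p = 0.0626, 0.058 and 0.0742. Eosinophil markers (median 0.42, camera adjusted p = 0.365) and basophil markers (1 higher and 1 lower of 12, adjusted p = 0.646) showed no list shift, and the basophil median of 0.01, with a camera direction of lower, turned to -0.01 with RLE scaling.

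By 4 h the Il4 difference had opened and chemokines were broadly lower. Il4 was 1225 ± 66.0 CPM in libraries labelled TTP-KO against 785 ± 40.4 CPM in WT (0.64 ± 0.07, edgeR adjusted p = 4.19e-05). Hbegf was higher by 0.77 ± 0.09 and Ccl3 by 0.32 ± 0.05, while Il13 was at -0.10 ± 0.05 (adjusted p = 0.377). Ccl22, a ligand of CCR4, was 4.59 ± 0.82 against 21.3 ± 1.29 CPM (-2.20 ± 0.22, adjusted p = 7.52e-08). Ccl24 was at -0.98 ± 0.14 and Il3 at -1.37 ± 0.25. The cytokine gene Osm (-0.82 ± 0.11) and the feedback regulators Socs1 (-0.56 ± 0.06) and Socs3 (-0.56 ± 0.07) were lower. The leading increases were Plekhg2 (1.61 ± 0.16), the ectoenzymes Cd38 (1.27 ± 0.19) and Enpp1 (1.26 ± 0.27), and the calprotectin genes S100a8 (1.16 ± 0.17) and S100a9 (1.12 ± 0.15). Then came Camp (1.08 ± 0.13), Ltf (1.04 ± 0.08), the chemokine Cxcl14 (0.98 ± 0.14) and Chchd10 (0.95 ± 0.18). The leading decreases were the immunoglobulin segment Ighv9-3 (-3.24 ± 0.48), Ccl22, Spib (-1.47 ± 0.21), Enah (-1.44 ± 0.23), the aldo-keto reductase Akr1c12 (-1.41 ± 0.16), the B cell coactivator Pou2af1 (-1.38 ± 0.28), Il3 and Asb2 (-1.33 ± 0.10). The comparison called 735 genes (257 higher, 478 lower, 47 at least 2-fold), 466 without replicate 2 of WT at 4 h, 484 without replicate 3 of TTP-KO at 4 h and 1130 with the spread taken from these 6 libraries alone. A further 3 genes the rule took lost their calls when single libraries were left out.

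Of 21 chemokines 11 were lower at 4 h and 2 higher (12 and 3 adjusted over the list alone, median -0.29, camera adjusted p = 7.04e-10). Cytokine signalling feedback had 5 lower of 20 and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 1.83e-08), with Id1 at -0.68 ± 0.07 and Bcl6 at 0.56 ± 0.13. Immediate early genes had 8 lower and 1 higher of 33 (12 and 1 adjusted over the list alone, adjusted p = 9.78e-07), Ier3 at -0.48 ± 0.05 and Dusp2 at -0.42 ± 0.07. NF-kB targets had 8 lower of 30 (the same adjusted over the list alone, adjusted p = 5.75e-05), Traf1 at -0.51 ± 0.10. Granule and exocytosis genes had 7 lower and 1 higher of 23 (8 and 2 adjusted over the list alone, adjusted p = 9.07e-05), Gzmb at -0.71 ± 0.09 and the membrane fusion protein Snap23 at -0.42 ± 0.05. Cell cycle genes were higher as a list (3 of 35, the same adjusted over the list alone, median 0.14, adjusted p = 2.80e-04). The reported tristetraprolin targets now had 2 higher and 8 lower of 33 (4 and 10 adjusted over the list alone, Lif -0.63 ± 0.10 and Ccl2 -0.65 ± 0.11), with camera adjusted p = 0.00202 and adjusted p = 0.217 with an estimated correlation. Cytokines had 3 higher and 6 lower of 26 (5 and 9 adjusted over the list alone, camera adjusted p = 0.0233, adjusted p = 0.322 with an estimated correlation). This call ended without replicates 2 or 3 of WT or replicate 3 of TTP-KO at 4 h (0.0506, 0.221 and 0.325).

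Several marker lists moved at 4 h beside these groups. Neutrophil genes had 10 higher and 1 lower of 17 (12 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 2.54e-20). Monocyte and macrophage genes had 10 higher and 1 lower of 16 (11 and 1 adjusted over the list alone, adjusted p = 1.46e-16), with Mrc1 at 0.87 ± 0.07 and Mertk, a receptor for dying cells, at 0.61 ± 0.10. Class II genes again made up the 4 lower of 8 dendritic cell markers (the same adjusted over the list alone, H2-Eb1 -0.75 ± 0.05, adjusted p = 5.95e-23). T and B cell genes had 5 lower of 9 (7 adjusted over the list alone, adjusted p = 5.43e-09), and mast cell markers had 2 lower and 1 higher of 8 (3 and 2 adjusted over the list alone, Tpsb2 -0.81 ± 0.06, adjusted p = 4.00e-04). Basophil markers had 6 lower of 12 (9 and 1 higher adjusted over the list alone, median -0.15, Cd200r4 -0.25 ± 0.05), with camera adjusted p = 2.15e-05 and adjusted p = 0.0978 with an estimated correlation. Natural killer and innate lymphoid markers (no call among 7, 3 lower adjusted over the list alone, camera adjusted p = 0.11) did not shift as a list. Nor did haematopoietic progenitor markers (1 lower of 10, 2 adjusted over the list alone, Gata1 -0.27 ± 0.06, adjusted p = 0.577).

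**Figure D4:**
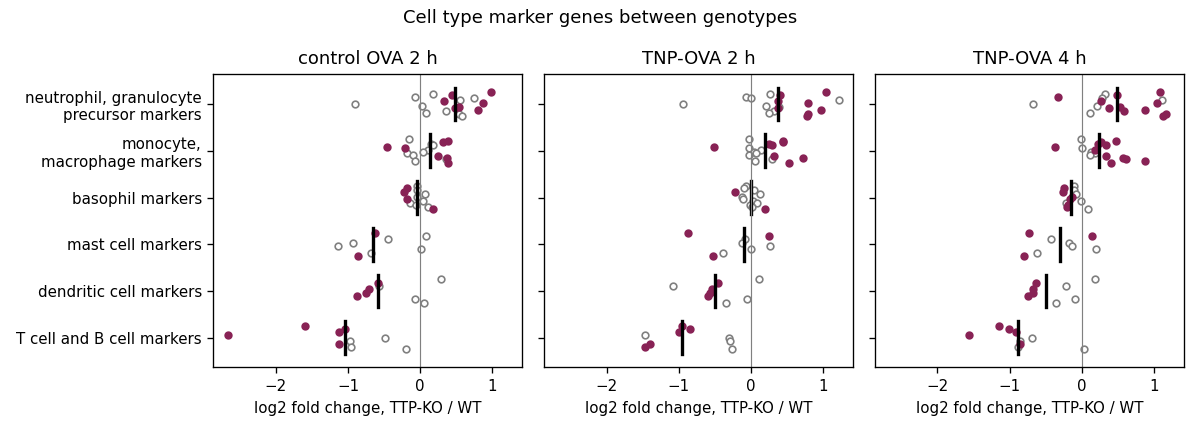
Log2 fold change (libraries labelled TTP-KO over WT, horizontal axis) of each measured gene in 6 lists of cell type markers (vertical axis), for control OVA, 2 h and 4 h of TNP-OVA. Filled points passed the edgeR test, open points did not, and black bars are list medians, which for neutrophil genes are 0.49, 0.38 and 0.49 and for T and B cell genes -1.04, -0.96 and -0.89.

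The remaining lists at 4 h passed camera with the preset correlation only or not at all. Surface receptors had 10 lower and 3 higher of 35, with Cd69 at -0.62 ± 0.08 (adjusted p = 0.0526 with an estimated correlation). IgE receptor signalling had 7 lower and 2 higher of 38, with the inhibitory receptor Lilrb4a at -0.38 ± 0.04 (adjusted p = 0.194 with an estimated correlation, and camera adjusted p = 0.0569 without replicate 3 of TTP-KO at 4 h). Another 4 lists were lower by camera with the preset correlation only. These were cholesterol synthesis (adjusted p = 0.0842 with an estimated correlation, and camera adjusted p = 0.0657 without replicate 3 of TTP-KO at 4 h) and the unfolded protein response (Sesn2 -0.63 ± 0.08, 0.0842 with an estimated correlation, and camera adjusted p = 0.0609 and 0.0936 without replicate 3 of WT or replicate 2 of TTP-KO at 4 h). The others were erythroid markers (adjusted p = 0.0831 with an estimated correlation, and 0.106 with no expression filter) and platelet markers (adjusted p = 0.288 with an estimated correlation, and 0.0506 without replicate 2 of WT at 4 h). No shift was called for the interferon response (camera adjusted p = 0.926), the calcium and NFAT pathway (0.368) or messenger RNA decay regulators (0.422). The same held for lipid mediators and histamine (0.937, with Alox5 at -0.27 ± 0.04), glycolysis (0.842, with the glucose transporter Slc2a3 at -0.39 ± 0.05) and eosinophil markers (0.577).

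The genotype differences overlapped between conditions, which share no libraries. The labels do not say whether libraries of different conditions came from separate animals or cultures. All 3 comparisons also took their spread from 1 fit. The counts for independent lists below are therefore a reference point and not a test. Of genes higher in libraries labelled TTP-KO, 29 were called both in control and at 2 h, where independent lists would share 0.53. In control and at 4 h 25 were shared (1.06 for independent lists), and at 2 h and 4 h 49 (2.34). Of genes lower, 76, 90 and 138 were shared, against 3.28, 5.91 and 9.0 for independent lists. In all 3 conditions 20 genes were higher, among them Camp, Ltf, Ngp and Plekhg2, and 60 were lower, among them Ccl22, Cd83, Cd79b, Tpsb2 and H2-Eb1. The call for Plekhg2 in control cells (0.74 ± 0.17, edgeR adjusted p = 0.0165) ended without replicate 3 of WT control or replicate 1 of TTP-KO control, at adjusted p = 0.115 and 0.127. That for Ccl22 at 2 h (-1.13 ± 0.28, adjusted p = 0.0239) ended without replicate 3 of WT or replicates 1 or 3 of TTP-KO at 2 h, at 0.145, 0.125 and 0.0784.

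Genes that antigen raised at least 2-fold in WT were on balance lower in the libraries labelled TTP-KO. The 742 genes raised at least 2-fold at 2 h in WT had 135 lower and 10 higher in the genotype comparison at 4 h, a comparison with none of the libraries that chose them (median -0.16, camera p = 1.00e-15, and 0.00114 with an estimated correlation). With no fold minimum, the 2512 genes raised had a median of -0.07 (camera p = 3.79e-10, p = 5.55e-04 with an estimated correlation). The 512 genes raised at least 2-fold at 4 h in WT had 44 lower and 13 higher in the genotype comparison at 2 h (median -0.08, camera p = 2.69e-04, and 0.0246 with an estimated correlation). With no fold minimum, the 2758 genes raised had a median of -0.02 (camera p = 0.0459, p = 0.0752 with an estimated correlation). The 309 genes lowered at 2 h had 5 higher and 5 lower at 4 h (median 0.09, camera p = 0.0258, p = 0.113 with an estimated correlation). Among the 391 genes lowered at 4 h, 1 was higher and 5 were lower at 2 h. That list did not shift (camera p = 0.907, p = 0.917 with an estimated correlation).

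Whether genotype altered the response itself was tested by interaction terms, the log2 fold change in libraries labelled TTP-KO minus that in WT. At 2 h 7 genes passed, 5 with a positive term, led by Il13 (0.58 ± 0.08, edgeR adjusted p = 6.80e-04), Rgs1, a regulator of G protein signalling (0.43 ± 0.06), and Ccl3 (0.55 ± 0.07). The other 2 had a negative term, led by Nr4a3 (-0.56 ± 0.08). At 4 h 97 genes passed, 39 with positive and 58 with negative terms, against 50 positive and 45 negative with only the libraries of the groups compared. Mrc1 (0.94 ± 0.10), fibronectin Fn1 (0.88 ± 0.11) and Dab2 (0.93 ± 0.12), genes of macrophages and adhesion, rose more in libraries labelled TTP-KO. Negative terms were found for the purinergic receptor P2ry1 (-0.60 ± 0.07), the thrombin receptor F2r (-0.49 ± 0.06), Akr1c13 (-1.05 ± 0.13), Coro2a (-0.85 ± 0.11) and Asb2 (-1.23 ± 0.16). Between 2 h and 4 h the change differed for 44 genes, 13 with positive and 31 with negative terms. Il4 (0.63 ± 0.10) fell less and Il13 (-0.65 ± 0.08) fell more in libraries labelled TTP-KO. These counts moved with the libraries used: at 2 h 4 without replicate 2 of TTP-KO control or replicates 1 or 3 of TTP-KO at 2 h, and 5 positive and 4 negative with RLE scaling. At 4 h the count was 59 and 56 without replicate 2 of the WT or the TTP-KO control, 51 and 52 without replicates 2 and 3 of WT at 4 h, and 46 without replicate 2 of TTP-KO at 4 h. For the time term it was 29 and 25 without replicates 2 and 3 of TTP-KO at 2 h, 26 without replicate 3 of WT at 4 h and 29 without replicate 3 of TTP-KO at 4 h.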

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

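Tests of composition by marker lists and of reading on from Zfp36 into Plekhg2 were chosen only after the results were seen, while the exchanged labels were planned. The results below are those whose response to antigen, or change from 2 h to 4 h, differed between WT and libraries labelled TTP-KO by an interaction term of the edgeR model. Each value is the difference of log2 fold changes, TTP-KO minus WT.

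At 2 h the differences were 0.58 for Il13, 0.43 for Rgs1, 0.55 for Ccl3 and -0.56 for Nr4a3. Zfp36 gave 0.41, Phf20l1 0.34 and Tufm -1.15, and leaving out most of the single libraries ended these calls, with edgeR adjusted p up to 0.117, 0.186 and 0.141. At 4 h the positive differences were 0.94 for Mrc1, 0.88 for Fn1, 0.93 for Dab2, 0.42 for Sdc4, 0.37 for Lpl and 0.77 for Rnf125, which antigen lowered in WT. The negative differences at 4 h were -0.60 for P2ry1, -1.05 for Akr1c13, -0.49 for F2r, -0.85 for Coro2a, -1.23 for Asb2 and -0.65 for Ccnd2. From 2 h to 4 h the differences were 0.82 for Mrc1, 0.33 for Kctd12, 0.70 for Fn1, 0.59 for Dab2, 0.63 for Il4, -0.65 for Il13, -0.48 for F2r, -0.98 for Akr1c13, -0.38 for Ccl6, -0.50 for Socs1 and -0.42 for Ier3. Ptgr3 gave 0.55, with edgeR adjusted p of 0.059, 0.0505, 0.0562 and 0.0549 without replicate 2 of WT at 2 h, replicates 2 or 3 of WT at 4 h or replicate 3 of TTP-KO at 4 h.

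Of 100 draws that exchanged genotype labels within conditions, 5, the real labels included, gave as many interaction genes at 2 h (7, highest other 127), as did 5 at 4 h (97, highest other 900) and 5 between 2 h and 4 h (44, highest other 190). The 4 other draws as large in each test all kept 1 condition as labelled and exchanged labels in the other, most of them in part, so the genotype difference itself entered their interaction. The 84, 84 and 80 draws with labels exchanged in both conditions called at most 1, 1 and 2 genes, but exchanged labels also widen the spread within groups. These draws therefore do not decide whether chance gives such counts.

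Markers of other blood cells shifted between genotypes in all 3 conditions, neutrophil genes upward and T and B cell genes downward. A lower share of basophils with all other cells alike would raise both lists, but they parted by 1.53, 1.34 and 1.38 log2 units between list medians, which argues against it. The cells had been enriched through CD49b, and varying shares of neutrophils or their precursors that remained may still contribute: deviations of neutrophil markers from their group means correlated across libraries at 0.105, above the 0.0646 that was the upper limit of random lists. Platelet markers gave 0.457 (limit 0.106), monocyte and macrophage markers 0.119 (limit 0.0898), eosinophil markers 0.116 (limit 0.113) and basophil markers 0.327 (limit 0.137). Varying shares of these cells, and not of neutrophils alone, may therefore contribute. Shared regulation within basophils, which was not tested, stays open as well, and these correlations do not tell the 2 apart. For T and B cell markers the correlation was 0.0361 against 0.118, and for dendritic cell markers 0.127 against 0.143, which leaves their source open.

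Plekhg2, the first gene downstream of Zfp36 on the same strand, was higher in libraries labelled TTP-KO. Transcription reading on from an altered Zfp36 allele is a candidate explanation: the excess of Plekhg2 over WT was 5.84, 16.5 and 12.9 CPM, and its ratio of 2 h to control, 2.83, lay near that of Zfp36, 2.52, while at 4 h the ratios were 2.21 and 1.45.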

How the results depend on the processing

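No called result for a named gene or a list reversed direction under the alternatives run. Changes of sign in named genes without a call were not counted. List medians near 0 without a call changed sign with RLE scaling. Of 561 results for named genes 531 were called, and 418 of these passed in every alternative run for them. Of 145 list results 68 were called and 36 passed in every alternative run for them. These gene and list results were not refitted with only the libraries compared, and the lists were not tested with DESeq2. Leaving out a library ended calls in 388 of the gene fits, no filter in 15, DESeq2 in 9, a replicate block in 8 and RLE in 4, and 18 gene results had no adjusted p in DESeq2. Between libraries of the same replicate number, deviations from group means correlated at -0.298 to 0.355. With 3 libraries in each group, this cannot show whether the numbers pair samples. The genotype counts were 257, 399 and 746 with a replicate block. With no filter the counts were 399 for genotype in control, 55, 259 and 134 for the interactions at 2 h, 4 h and over time. DESeq2 gave 22, 176 and 103 for these interactions. With only the libraries compared the counts were 149 for genotype in control, 1130 at 4 h and 11 for the interaction at 2 h. The larger of the directions changed in 7 fits. For the interaction at 4 h with only the libraries compared, 50 terms were positive and 45 negative, in place of 39 and 58. With no filter 2355 were higher and 2475 lower in WT at 2 h, 2358 and 2416 in TTP-KO at 2 h, and from 2 h to 4 h 2401 and 1923 in WT and 2221 and 1995 in TTP-KO. Without replicate 2 of WT at 4 h 2277 were higher and 2371 lower in WT at 4 h, and with only the libraries compared 2571 and 2616 in TTP-KO at 4 h; the cause was not tested. Leaving out single libraries gave 145 to 190 genes for genotype in control, 228 to 369 at 2 h, 466 to 551 at 4 h, and 4 to 8, 46 to 133 and 25 to 53 for the interactions. With an estimated correlation 6, 7 and 11 lists passed between genotypes in control, at 2 h and at 4 h, in place of 12, 15 and 20, and 5 in WT at 4 h in place of 10. By fry 21 and 23 lists passed in WT at 2 h and 4 h. WT-repressed genes at 4 h had p = 0.113 with an estimated correlation. Fewer libraries leave fewer degrees of freedom; otherwise the cause was not tested. At this depth and spread, 65 of 100 simulated 1.5-fold changes were found among genes with a mean log2 CPM of at least 2.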

Other observations

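Splits of the libraries and tests of the motif and of the interval around Zfp36 were planned, and the genes named in the first paragraph were chosen after their values were seen. Lower in libraries labelled TTP-KO in all 3 conditions were Nr1d1, a repressor of the circadian clock, by a log2 difference of -0.82 ± 0.12 in control, -0.82 ± 0.13 at 2 h and -0.86 ± 0.12 at 4 h, and Ciart by -0.82 ± 0.17, -0.83 ± 0.17 and -0.90 ± 0.16. Il4i1, a secreted amino acid oxidase, was at -0.76 ± 0.10, -1.02 ± 0.09 and -0.80 ± 0.08. Higher in all 3 were the membrane protease gene Mmp14, at 0.55 ± 0.06, 0.60 ± 0.06 and 0.56 ± 0.06, and Mpo, myeloperoxidase, at 0.49 ± 0.07, 0.38 ± 0.07 and 0.38 ± 0.07.

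For the comparisons of 3 libraries with 3, the 10 splits of each are too few for a share under 0.05. Only 1 split, the real one, reached its count in each. Every other split exchanged 1 library of each group, which widens the spread within groups where the groups differ. Low counts in those splits therefore do not decide whether chance gives the real counts. Between genotypes the real counts and the highest of the other splits were 232 and 1 in control, 393 and 3 at 2 h and 735 and 0 at 4 h. For stimulation they were 4944 and 6 in WT at 2 h, 5350 and 1 in WT at 4 h, 4852 and 0 in TTP-KO at 2 h and 4932 and 0 in TTP-KO at 4 h, and from 2 h to 4 h 4382 and 1 in WT and 4334 and 0 in TTP-KO.

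Genes higher in libraries labelled TTP-KO were searched for UAUUUAU, a tristetraprolin-type motif, in their 3' UTRs. It was present in 28.3%, 26.05% and 33.3% of those called in control, at 2 h and at 4 h, where matched random genes had medians of 24.5%, 21.8% and 30.1% and upper limits of 34.0%, 29.4% and 35.4%. These shares lay above the medians and inside the limits, so binding through this motif may or may not contribute and stays open. Genes lower in libraries labelled TTP-KO had shares of 32.1%, 29.4% and 32.7%, against matched medians of 29.0%, 31.7% and 30.5%. Their upper limits were 35.8%, 36.9% and 34.1%. A share above the median was therefore not particular to the higher genes in control and at 4 h. The test found 20 of 20 simulated sets of 150 genes with tripled odds of the motif and 1 of 20 random sets. The sets of higher genes held 53, 119 and 246 genes with a 3' UTR. How well the test finds smaller enrichments, or works in a set as small as that in control, was not measured.

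Effects of a strain interval around Zfp36 on genes within it were argued against as the main source of the genotype calls. Within 20 Mb lay 3.51%, 3.59% and 2.76% of calls, against 3.01% of tested genes (Fisher's exact p = 0.559, 0.452 and 0.823, two-sided). This count cannot detect effects of such an interval on genes elsewhere.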
